A study of Enterococcus faecalis with 39 samples.

How the data were processed

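RNA sequencing libraries from Enterococcus faecalis exposed to the bacteriocin glycocin F (GccF), to N-acetylglucosamine (GlcNAc) or to neither were analysed in 39 samples that form 13 groups of 3. Total RNA was isolated with Trizol and a column kit after bead milling, depleted of bacterial rRNA with RiboZero and made into stranded TruSeq libraries, per the labels' protocols. The authors deposited raw read counts per feature, with 1 file per sample and no normalization. Reads were aligned with Bowtie2 2.2.9 and counted with HTSeq 0.6.0, per the submitters' processing notes. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so features that overlap or lie antisense to each other carry uncertain counts. Reads of multiple alignment are at 0 in every file, so how the counting treated near-identical copies could not be read from the files.

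The deposited counts of the 33 JH2-2 libraries cover 2826 features, of which 2750 identifiers begin with ERT and 76 with O994_. The counts of the 6 VI01 libraries cover 3461 features, of which 3265 begin with AAO, 116 with EBG and 68 are named as tRNA rows, with 12 rRNA rows in addition. No identifier occurs in both strains' files. The files do not pair identifiers with gene names, and no annotation was used here. For that reason at most 2 features that rose and 2 that fell are named per comparison, by identifier. Gene list tests, 3 comparisons across strains that were planned before the data were examined, and a check of the gene knocked out in VI01 were not made. VI01 was fitted alone for the same reason, and the fits planned over 18 and 39 samples hold the 12 and 33 JH2-2 libraries instead.

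Each file ends with 5 summary rows, which were kept out of library sizes and tests. In JH2-2 libraries, reads outside features took 6.33% to 11.2% of all reads, reads between overlapping features 2.34% to 3.66%, low-quality alignments 0.398% to 6.49% and unaligned reads 0.232% to 7.53%. In VI01 libraries the corresponding shares were 5.91% to 7.58%, 3.52% to 4.42%, 7.93% to 12.4% and 3.81% to 11.2%. Counted reads per library ran from 6724023 to 9689748 in JH2-2 and from 6257222 to 8933323 in VI01, and 93 to 143 and 427 to 482 features had no count.

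Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were filtered by edgeR's default expression filter with the groups given, and library sizes were scaled by TMM. A negative binomial model with 1 mean per group was fitted, and contrasts were tested with the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values, and a feature is said to have risen, fallen or changed where its adjusted p lay under 0.05. Standard errors of log2 fold changes were derived from the F statistic. The 21 libraries of the time course (7 groups) were fitted together with 14 residual degrees of freedom, the 12 libraries of the 20 nM set (4 groups) with 8, the 6 VI01 libraries with 4, and all 33 JH2-2 libraries with 22 for the comparison of doses. The square root of the common dispersion was 0.143, 0.294, 0.156 and 0.212 in these fits. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Replicates of a group differed by far more than counting noise, with a chi-square per degree of freedom of 11.5 to 593, so each library was counted once.

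The rule for named features took those with adjusted p under 0.05, a change of at least 2-fold and no overlap between the groups' replicates (the last condition left out for a difference of effects), and ranked them by fold change. The 12 largest rises and falls per comparison were planned, and only the leading ones are printed. Levels are given as TMM-scaled CPM, mean ± SD with n = 3. To place libraries on 1 axis, a response score was computed from the features that changed at least 2-fold after 30 min of 250 nM GccF. It was the mean log2 CPM (prior count 2) of the 655 that rose minus that of the 520 that fell. It was chosen after the data were examined, and it is circular for the control and GccF libraries at 30 min of the time course. Score differences were tested with exact two-sided permutation tests. With 3 against 3 libraries these cannot give a p below 0.1.

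The replicate numbers of the labels were examined for pairing through correlations, across features, of deviations from the group means. Same-numbered libraries correlated above 0.1 in all 3 pairs for 20 nM GccF after GlcNAc and its control (lowest r = 0.126), for both untreated groups of the 20 nM set (lowest r = 0.388), for both treated groups of that set (lowest r = 0.458) and for VI01 (lowest r = 0.165). For 20 nM GccF without GlcNAc and its control the lowest r was 0.0267, so the test of the difference made by GlcNAc, which spans all 4 groups, was not treated as paired, while controls of the GlcNAc set and 20 nM GccF met the minimum (lowest r = 0.146). In the time course no comparison between treated and untreated libraries met it, and the controls at 10 and 30 min did (lowest r = 0.101). The control of the GlcNAc set is called untreated because it had no GccF, while whether it contained GlcNAc is not stated.

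Alternatives were scaling by median-of-ratios factors, by the upper quartile or by totals, no filter and a filter of at least 10 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, fits on the compared groups or on all 33 JH2-2 libraries, a replicate block, removal of tRNA and rRNA rows in VI01, and leaving out each library. Added after the data were examined were removal of O994_ rows and leaving out the libraries numbered 2 in the 20 nM set. The pipeline was tested on simulated counts with known changes. For 250 nM GccF at 30 min, over 2505 features, it recovered 94% of 2-fold and 100% of 4-fold changes. For 20 nM GccF, over 2490 features, it recovered 40% and 94%, and for the difference made by GlcNAc, over 2491 features, 12% and 74%. Of the calls in these simulations 5.82%, 5.6% and 5.10% were false. Each simulation changed a small part of the features, equally up and down (50 of them 2-fold). The real comparison at 30 min of 250 nM called 1918 of 2530 features, so recovery and scaling there may differ from the simulation. Figures were drawn with matplotlib 3.10.9.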

Results

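Transcript levels were measured in 2 strains of Enterococcus faecalis after exposure to GccF, a glycosylated antimicrobial peptide that carries GlcNAc residues. Strain JH2-2 was sampled at 0, 10 and 30 min with 250 nM GccF or without it, and at 10 min with 1 mM GlcNAc alone, giving 21 libraries of a time course. A further 12 libraries of JH2-2 compared 20 nM GccF at 30 min with a control, and 20 nM GccF after GlcNAc with a control of its own. The last 6 libraries came from VI01, a strain labelled as a sigma-54 knockout, with 100 nM GccF for 30 min or untreated. The harvest time of the controls outside the time course, and whether the control of the GlcNAc set contained GlcNAc, are not stated. Depth ran from 6724023 to 9689748 counted reads per JH2-2 library and from 6257222 to 8933323 per VI01 library. Features are given by the identifiers of the count files, which do not pair them with gene names.

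**Figure D1:**
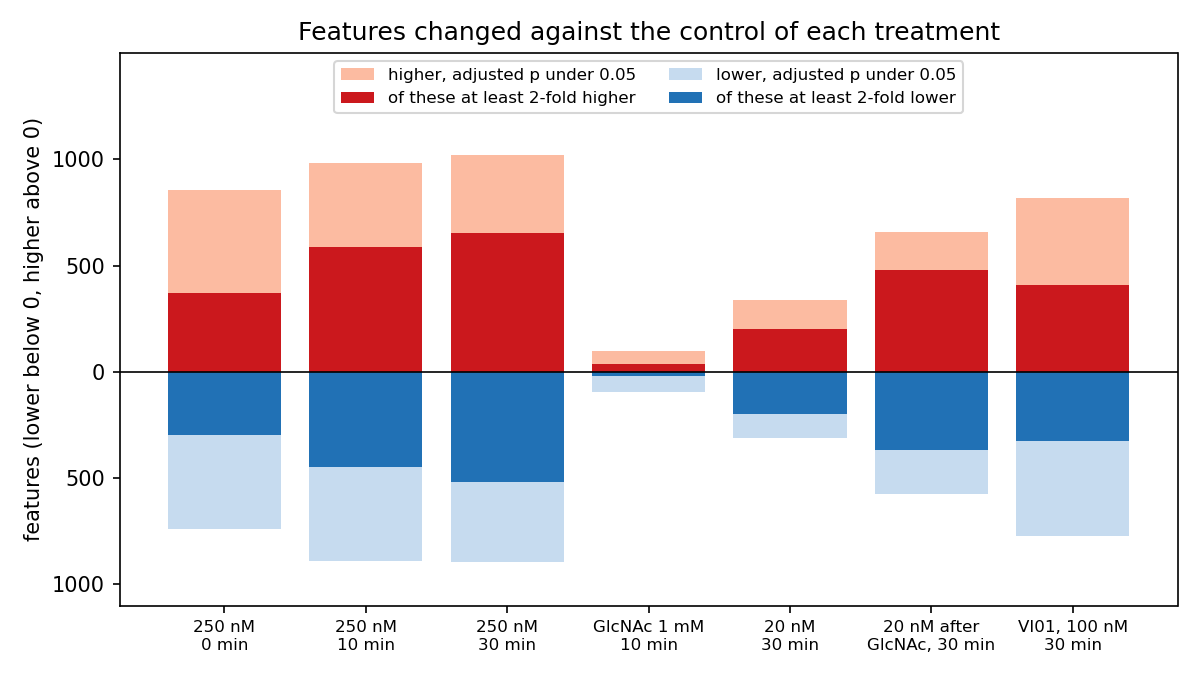
Features that changed against the control of each treatment (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 per group), with higher features above 0 and lower ones below. Dark bars are the part changed at least 2-fold. With 250 nM GccF at 30 min 1022 features rose and 896 fell, and with GlcNAc alone 99 rose and 97 fell. Spread and the share of simulated changes recovered differed between the sets, which limits comparison of the counts.

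The time course asks how the response to 250 nM GccF developed. After 30 min, feature ERT21738-1 stood at 2551 ± 68.7 CPM with GccF and at 3.39 ± 0.461 CPM without (SD, n = 3), a log2 fold change of 9.55 ± 0.26 (SE; adjusted p = 2.11e-18, edgeR). ERT23105-1 rose from 0.628 ± 0.00633 to 76.6 ± 11.9 CPM, a 119-fold increase. Its control level rested on 15 reads over the 3 libraries, so this fold is imprecise and the small SD says little. The largest falls were those of ERT23251-1, from 80.3 ± 26.4 to 0.894 ± 0.149 CPM, and ERT23249-1, from 104 ± 14.9 to 1.34 ± 0.246 CPM, which were 88.0-fold and 76.4-fold. Altogether 1022 features rose and 896 fell among 2530 tested, and 655 and 520 of them changed at least 2-fold. The 12 largest rises had log2 fold changes of 5.07 to 9.55 and the 12 largest falls of -6.46 to -4.95. Upper-quartile scaling moved the median of all features by -0.204 on the log2 scale at this time and by -0.232 at 10 min, so directions of small changes depend on the scaling. In each comparison with calls, except the GlcNAc difference at 20 nM, another scaling turned which direction held more calls, as upper-quartile scaling did here with 887 features higher and 1056 lower.

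The response was already large at 10 min. ERT21738-1 reached 1628 ± 287 CPM against 14.97 ± 1.36 CPM in the control, and ERT23105-1 reached 95.0 ± 11.8 CPM against 0.788 ± 0.204 CPM, with log2 fold changes of 6.76 ± 0.22 and 6.88 ± 0.21 (SE; adjusted p = 9.46e-17 and 5.14e-17, edgeR). ERT24749-1 fell from 23.4 ± 1.89 to 0.374 ± 0.121 CPM and ERT24743-1 from 14.9 ± 2.22 to 0.264 ± 0.243 CPM. These low levels rested on 8 and 6 reads per group, and the control level of ERT23105-1 on 18, so the sizes of these changes are imprecise. In all, 982 features rose and 891 fell, 587 and 449 of them at least 2-fold.

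Libraries labelled 0 min also differed between GccF and control. ERT21738-1 was at 510 ± 57.9 CPM with GccF and 20.97 ± 5.09 CPM without, and ERT23105-1 at 10.2 ± 0.755 against 0.390 ± 0.00795 CPM. The control level of ERT23105-1 rested on 9 reads over the 3 libraries. Lower with GccF were ERT25488-1, at 13.7 ± 3.54 against 483 ± 42.2 CPM (log2 fold change -5.14 ± 0.23 SE, adjusted p = 5.53e-14, edgeR), and ERT24749-1, at 1.37 ± 0.797 against 18.4 ± 3.29 CPM. A total of 854 features rose and 741 fell, 369 and 299 of them at least 2-fold. The labels do not say how long after addition these cells were collected. Scaling by the upper quartile or by totals moved the median of all features by -0.117 or by 0.119 at this time.

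**Figure D2:**
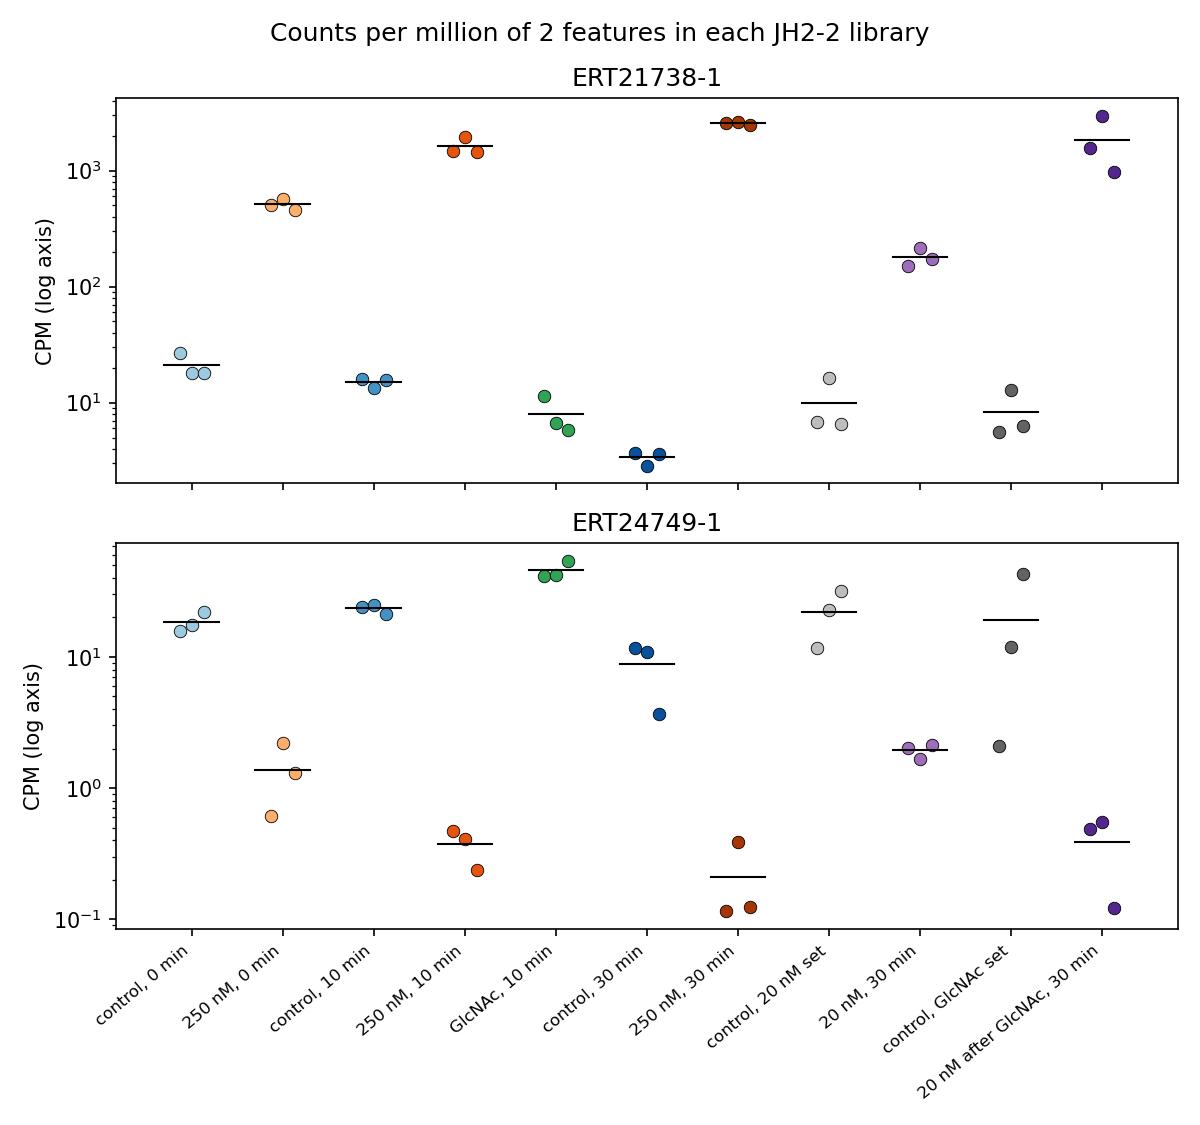
CPM of ERT21738-1 (top) and ERT24749-1 (bottom) in each of the 33 JH2-2 libraries, on log axes. Each point is a library and each line the mean of 3 libraries of a group. ERT21738-1 was at 2551 CPM after 30 min of 250 nM GccF and at 3.39 CPM in the control of that time, and ERT24749-1 lay lower in every GccF group than in its control group on average.

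Tests of the difference between times covered the same 2530 features. Between 0 and 10 min the GccF effect changed for 1032 features (576 upwards, 456 downwards). It grew in the same direction in 562, shrank in 123, and the estimates had opposite signs in 347. Signs were taken without asking that either effect was called. Among all features tested, 48 were called up at 0 min and down at 10 min, and 43 the reverse. Upper-quartile scaling put 45.6% of the changes in effect upwards, where TMM put 55.8%. The largest upward differences were those of ERT25456-1 and ERT21274-1, at 3.51 ± 0.66 and 3.37 ± 0.40 log2 units (SE; adjusted p = 0.000208 and 1e-06, edgeR). For ERT21274-1 this was a fall at 0 min, to 164 ± 42.6 CPM with GccF against 1424 ± 205 CPM in the control, with no call at 10 min (adjusted p = 0.399), where means were 1580 ± 836 and 1320 ± 178 CPM. ERT25456-1 was near the floor, at 0.190 ± 0.121 CPM with GccF at 0 min against 1.21 ± 0.251 CPM, and at 3.24 ± 0.765 against 1.65 ± 0.670 CPM at 10 min. ERT24628-1 had the largest downward difference, of -4.38 ± 0.41, being at 118 ± 59.1 CPM with GccF at 0 min and at 5.61 ± 2.21 CPM at 10 min, with controls at 41.8 ± 6.93 and 41.6 ± 7.88 CPM. Between 10 and 30 min the effect changed for 677 features (329 upwards, 348 downwards), of which 314 grew, 179 shrank and 184 had estimates of opposite signs. Among all features tested, 36 were called up at 10 min and down at 30 min, and 18 the reverse. For the change in effect, upper-quartile scaling called 372 upwards and 325 downwards and scaling by totals 251 and 382. A fit with all 33 JH2-2 libraries called 318. ERT25445-1 led, with a log2 difference of 5.67 ± 0.44 (SE, adjusted p = 2.72e-09), followed by ERT25446-1 at 5.20 ± 0.27. ERT20956-1 and ERT24751-1 lay at the other end, with log2 differences of -4.88 ± 0.35 and -4.08 ± 0.91. In these 4 features mainly the control moved. From 10 to 30 min ERT25445-1 went from 117 ± 21.5 to 2.94 ± 2.42 CPM in controls and from 127 ± 49.7 to 164 ± 11.7 CPM with GccF, and ERT25446-1 from 120 ± 13.5 to 4.82 ± 1.49 and from 87.6 ± 12.02 to 130 ± 5.63 CPM. ERT20956-1 went from 21.2 ± 3.57 to 384 ± 165 CPM in controls and from 27.8 ± 1.29 to 17.0 ± 0.855 CPM with GccF, and ERT24751-1 from 2.09 ± 0.737 to 26.5 ± 14.0 and from 0.724 ± 0.521 to 0.562 ± 0.341 CPM.

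Sorted by the 3 times, 556 features rose at each of them and 447 fell at each of them. A further 113 changed at each time with mixed direction, and 174 changed at none. Changes at 0 and 30 min, which share no library, correlated with r = 0.616 across features, which are not independent replicates. Of the features called at both of these times, 591 rose and 476 fell at both, where independent lists would give 345 and 262. Another 200 had opposite directions. Between 10 and 30 min the correlation was 0.871.

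Untreated cells drifted over the same period. In controls, ERT20811-1 rose from 20.4 ± 7.18 CPM at 0 min to 514 ± 180 CPM at 30 min, and ERT20810-1 from 4.72 ± 1.78 to 95.7 ± 37.7 CPM. ERT25445-1 fell from 248 ± 50.7 to 2.94 ± 2.42 CPM and ERT25446-1 from 167 ± 28.9 to 4.82 ± 1.49 CPM, log2 fold changes of -6.39 ± 0.36 and -5.12 ± 0.21 (SE; adjusted p = 9.7e-12 and 5.24e-14, edgeR). In all, 407 features rose and 480 fell, 105 and 92 at least 2-fold. Scaling by totals put 59.2% of the calls upwards, where TMM put 45.9%, and the count of 887 was 566 without replicate 1 of the control at 0 min and 522 in a fit of all 33 JH2-2 libraries.

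GlcNAc alone, the sugar that GccF carries, changed few features within 10 min. ERT23545-1 rose from 573 ± 46.7 to 4127 ± 502 CPM and ERT23544-1 from 64.8 ± 12.7 to 538 ± 48.3 CPM (log2 fold changes 2.85 ± 0.13 and 3.06 ± 0.17 SE; adjusted p = 3.98e-13 and 7.78e-12, edgeR). ERT21673-1 fell from 2274 ± 267 to 253 ± 27.2 CPM and ERT23150-1 from 159 ± 37.4 to 17.5 ± 1.28 CPM. In total 99 features rose and 97 fell, 37 and 22 at least 2-fold. Leaving out replicate 1 of the control, or replicate 1 or 3 of the GlcNAc group, lowered the count from 196 to 93, 129 or 98, and a fit with all 33 libraries gave 79.

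The changes by GlcNAc did not run parallel to those by GccF at 30 min in other libraries, with r = 0.00467 across features. Among features called in both comparisons, 64 fell in both and 59 rose with GlcNAc and fell with GccF, where independent lists would give 34.4 and 35.1, while 31 rose in both (39.99) and 20 fell with GlcNAc and rose with GccF (39.2). Tested directly at 10 min, GccF and GlcNAc libraries differed in 1836 features, with 981 higher and 855 lower with GccF. ERT21738-1 was at 7.98 ± 3.04 CPM with GlcNAc, a log2 difference of 7.67 ± 0.23 from GccF (SE, adjusted p = 2.98e-17, edgeR). ERT24749-1 was at 45.8 ± 7.02 CPM with GlcNAc and at 0.374 ± 0.121 CPM with GccF, and upper-quartile scaling moved the median of all features in this comparison by -0.230.

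**Figure D3:**
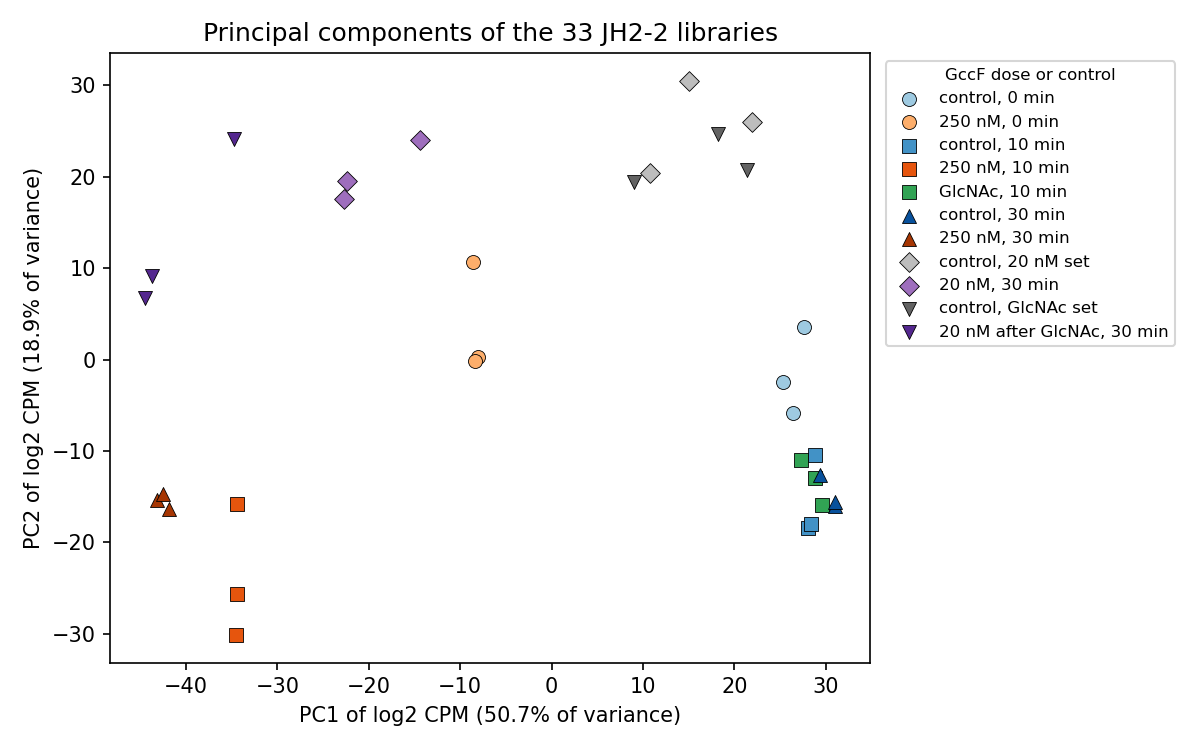
Principal components 1 and 2 of log2 CPM in the 33 JH2-2 libraries, with a symbol per library and the share of variance on each axis (50.7% and 18.9%). Controls and GlcNAc lie at positive values of component 1 and all GccF libraries at negative values, while component 2 sets the 12 libraries of the 20 nM set apart from the other libraries with a similar value of component 1.

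At 20 nM, GccF for 30 min raised ERT21738-1 from 9.85 ± 5.47 to 180 ± 33.2 CPM and ERT20732-1 from 2.74 ± 1.52 to 42.7 ± 20.97 CPM, with log2 fold changes of 4.18 ± 0.52 and 3.97 ± 0.62 (SE; adjusted p = 0.000263 and 0.000859, edgeR). ERT23254-1 fell from 334 ± 109 to 14.5 ± 10.9 CPM. ERT20811-1 fell from 90.0 ± 102 to 3.30 ± 1.56 CPM, with its control replicates far apart. In total 336 features rose and 310 fell among 2511 tested, 200 and 201 at least 2-fold. The count of 646 was 402 or 428 without replicate 1 or 3 of the treated group and 976 in a fit of all 33 libraries. Changes by 20 and 250 nM at 30 min correlated with r = 0.818 across features in libraries that are not shared. Both comparisons called 316 features up and 277 down, against 136 and 110 for independent lists, and 7 features were called in opposite directions.

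The dose difference was tested over 2556 features as the effect of 250 nM minus that of 20 nM, each against the control of its own set. It passed the threshold in 882 features. In 652 of these the effect was larger at 250 nM in the same direction, in 25 it was smaller and in 205 the estimates had opposite signs. The signs were taken without asking that either effect was called. ERT21738-1 had a log2 difference of 5.23 ± 0.52 and ERT25445-1 of 5.19 ± 0.48 (SE; adjusted p = 4.05e-08 and 1.04e-08, edgeR), and ERT24751-1 and ERT20956-1 had differences of -4.70 ± 0.70 and -4.01 ± 0.36. For 3 of these the controls of the sets were far apart: ERT25445-1 stood at 2.94 ± 2.42 CPM in the control at 30 min and at 320 ± 51.9 CPM in that of the 20 nM set, ERT20956-1 at 384 ± 165 and 25.3 ± 4.40 CPM, and ERT24751-1 at 26.5 ± 14.0 and 3.32 ± 1.02 CPM. The harvest time of the 20 nM control is not stated. Dose and set therefore cannot be told apart here.

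Libraries labelled as 20 nM GccF after GlcNAc had a larger response than those with 20 nM GccF alone. ERT21738-1 reached 1840 ± 1033 CPM against 8.22 ± 3.98 CPM in the control of this set, and ERT21737-1 reached 1975 ± 699 against 37.3 ± 11.6 CPM (log2 fold changes 7.80 ± 0.61 and 5.73 ± 0.42 SE; adjusted p = 5.72e-06 and 4.24e-06, edgeR). ERT24749-1 fell from 19.0 ± 21.4 to 0.388 ± 0.233 CPM and ERT20811-1 from 121 ± 97.7 to 2.71 ± 1.21 CPM. The low level of ERT24749-1 rested on 10 reads over the 3 libraries. A total of 659 features rose and 575 fell, 479 and 370 at least 2-fold. Upper-quartile scaling moved the median of all features by -0.120. Changes by 20 nM GccF with and without GlcNAc correlated with r = 0.850 across features, and 297 features rose and 270 fell in both, against 88.2 and 71.0 for independent lists.

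**Figure D4:**
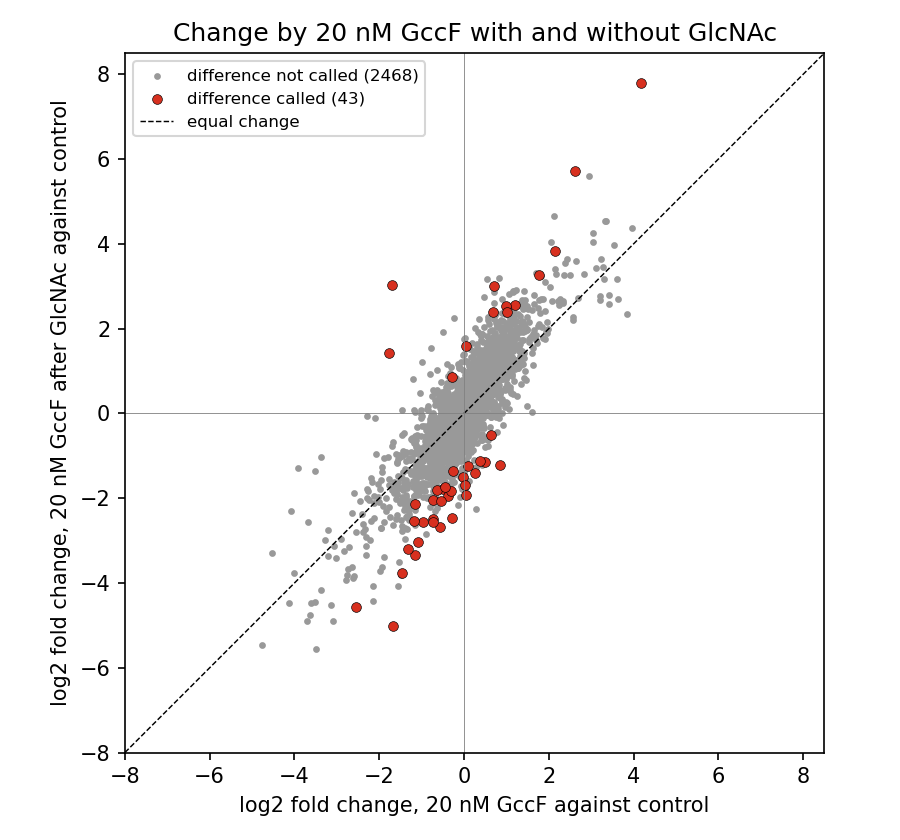
Log2 fold change by 20 nM GccF without GlcNAc (horizontal) and after GlcNAc (vertical), each against its own control, for 2511 features. The dashed line marks equal change. Red points are the 43 features whose changes differed in the test of the difference itself, and ERT21738-1 is the highest point.

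The test of that difference called 43 features. In 32 the effect was larger after GlcNAc in the same direction, in 11 the estimates had opposite signs, called or not, and in none was it smaller. ERT23842-1 and ERT21738-1 had log2 differences of 4.74 ± 0.74 and 3.62 ± 0.67 (SE; adjusted p = 0.0192 and 0.0256, edgeR), and ERT20801-1 and ERT21266-1 of -3.32 ± 0.64 and -2.32 ± 0.27 (adjusted p = 0.0272 and 0.00641). For ERT23842-1 part of the difference lay in the controls, at 1.63 ± 0.538 CPM in the GlcNAc set and 9.44 ± 5.81 CPM in the 20 nM set, and it stood at 13.4 ± 5.68 CPM with GccF after GlcNAc and fell to 2.90 ± 0.286 CPM with GccF alone. ERT21266-1 stood at 130 ± 9.68 CPM with GccF after GlcNAc, at 714 ± 89.5 CPM with GccF alone, and at 1773 ± 401 and 1956 ± 187 CPM in the controls. The count is unstable: leaving out any 1 of the 12 libraries moved it by over 1.5 times, to between 1 and 202, the latter without replicate 2 of GccF after GlcNAc. DESeq2 called 164 and a fit with the replicate number as a block 294. The adjusted p of ERT21738-1 ran up to 0.0890 over the alternatives, that of ERT20801-1 to 0.111 and that of ERT23842-1 to 0.0641.

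The features that changed at least 2-fold after 30 min of 250 nM GccF define the response score. This score, the mean log2 CPM of risen features minus that of fallen ones, gave the same order. It was 0.870 ± 0.210 with 20 nM GccF and 1.85 ± 0.1297 with 20 nM GccF after GlcNAc (SD, n = 3), and -0.878 ± 0.220 and -0.915 ± 0.236 in their controls. The 2 treated groups differed by 0.977 ± 0.14 (SE), without overlap between libraries (exact two-sided permutation p = 0.1, the smallest possible). At 0 min the score was 0.220 ± 0.0326 with 250 nM GccF and -1.34 ± 0.0379 in the control. At 10 min it was 1.48 ± 0.0333 with 250 nM GccF, -1.43 ± 0.0592 with GlcNAc alone and -1.49 ± 0.0193 in the control. Control levels differed between sets, so score levels should not be compared across them. Differences from the own control were 1.56 at 0 min and 2.96 at 10 min of 250 nM GccF, 1.75 with 20 nM GccF and 2.76 with 20 nM GccF after GlcNAc.

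**Figure D5:**
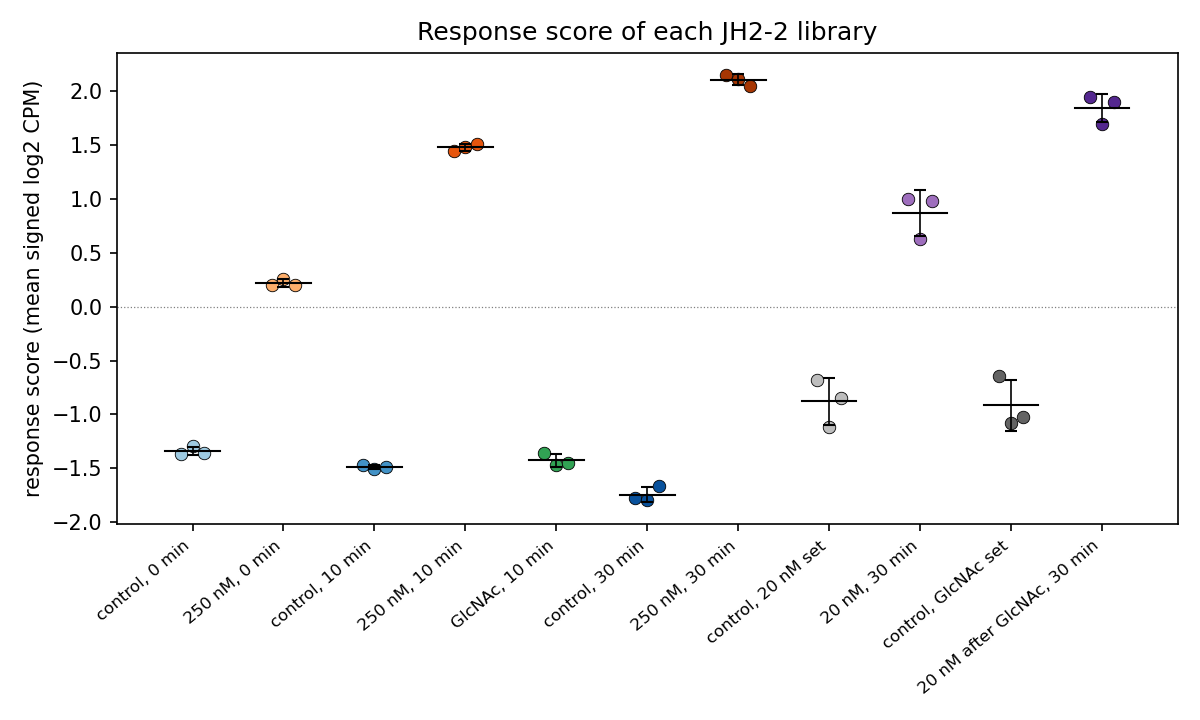
Response score of each of the 33 JH2-2 libraries by group. It is the mean log2 CPM of risen features minus that of fallen ones, though the axis is labelled mean signed log2 CPM. Points are libraries, and lines and bars the mean and SD of 3 libraries. The score lies between 1.70 and 1.94 with 20 nM GccF after GlcNAc and between 0.627 and 0.998 with 20 nM GccF alone. The features were chosen at 30 min of 250 nM GccF, so the control and GccF groups of that time are apart by construction.

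The groups without GccF in the 20 nM and GlcNAc sets were not separated by the test. No feature of 2511 passed in edgeR, 82 had an unadjusted p under 0.05 and DESeq2 called 5. With the replicate number as a block, edgeR called 1. ERT21738-1 stood at 8.22 ± 3.98 CPM in the control of the GlcNAc set and at 9.85 ± 5.47 CPM in that of the 20 nM set.

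In VI01, the sigma-54 knockout strain, 100 nM GccF for 30 min raised AAO81958-1 from 17.6 ± 10.9 to 1454 ± 106 CPM and AAO81321-1 from 8.34 ± 1.25 to 353.99 ± 16.4 CPM, with log2 fold changes of 6.35 ± 0.40 and 5.40 ± 0.16 (SE; adjusted p = 1.45e-06 and 6.99e-08, edgeR). AAO79959-1 fell from 2146 ± 226 to 47.3 ± 15.4 CPM and AAO79960-1 from 193 ± 6.74 to 6.54 ± 1.38 CPM. Among 2564 features tested, 819 rose and 773 fell, 410 and 325 at least 2-fold. TMM put 51.4% of the calls upwards, upper-quartile scaling 36.7% and scaling by totals 41.1%, with the median of all features moved by -0.239 and -0.166. Of 29 tRNA rows tested, 5 rose and 3 fell, or 4 and 4 with upper-quartile scaling. Neither of the 2 rRNA rows tested was called.

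The strains' identifiers do not match, so no feature was compared between VI01 and JH2-2. Fitted on the compared groups alone, 62.1% of the features tested changed with 100 nM GccF in VI01, 28.9% with 20 nM and 83.3% with 250 nM at 30 min in JH2-2. These shares come from different doses, sets, annotations and spreads, and their difference was not tested.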

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

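The tests of alignment, of replicate numbers, of the relation to 20 nM GccF, of the 1 library with low-quality alignments and of weaker exposure, the splits for 250 nM at 30 min and for the 2 untreated groups, the sorting of splits by treated libraries and by number 2, and the relation of control drift to 20 nM GccF, were chosen after the result was seen; the others were written before.

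The GccF effect differed between groups in 4 tests of the difference: 1032 features between 10 and 0 min, 677 between 30 and 10 min, 43 with against without GlcNAc at 20 nM, and 882 between 250 and 20 nM. Libraries were exchanged between the 2 conditions in 100 splits each, the real one included, and 8 of the other 99 kept the treated libraries of each condition together, so that they carried the difference between the treated groups. For 10 against 0 min 8 splits gave as many features (highest other 1372), of which 7 were such splits, and the highest count among the 91 that mixed treated libraries was 532. For GlcNAc 12 gave as many (highest other 538), of which 8 were such splits and 3 mixed the treated libraries. These 3 followed replicate number 2, with both treated libraries of that number on one side and both untreated ones opposite, and the block gave 294. Of the 8 splits that followed number 2, only these 3 gave as many, and the lowest called 0. Following that number therefore did not by itself give a high count. The highest count among the 83 mixing splits that did not follow it was 2. Taken over all 100 splits, chance stays undecided for these 2 counts. For 30 against 10 min and for the doses 3 and 2 splits gave as many (highest others 833 and 1127), a share under 0.05. Mixing puts libraries of different times or sets into 1 group, which can widen its spread, and most mixing splits called 0. The share therefore cannot exclude chance. For the doses a split that mixed treated libraries reached 854 against the real 882. For 30 against 10 min the highest such split called 214.

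For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split called 1595, 1873 and 1918 features for 250 nM at 0, 10 and 30 min, 1836 for GccF against GlcNAc, 887 for the controls over time, 646 and 1234 for 20 nM without and after GlcNAc and 1592 in VI01, and the highest other split 0 in each. For GlcNAc alone the real split called 196 and the highest other 1. For the 2 untreated groups the real split called 0, all 10 splits as many, and the highest 15. That split set replicate 2 of both groups and replicate 3 of the GlcNAc set against the rest, which held replicate 1 of both groups. It therefore cannot be assigned to 1 replicate number. Other splits that kept replicate 2 of both groups together called 0, and the block gave 1. Where the numbers pair the libraries, the other splits that part all 3 pairs called 0 for 20 nM GccF after GlcNAc, for VI01 and for the untreated groups.

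The larger response to 20 nM GccF after GlcNAc is unexpected, since free GlcNAc is known as a protectant against GccF. Uneven replicate numbers are argued against, since the score difference within a number was at least 0.916 (pooled SD 0.175). Poorer alignment of the libraries without GlcNAc is argued against too: their controls were aligned as poorly (1.61% to 7.53% unaligned, against 0.523% to 0.710% in the GlcNAc set), yet scores of the untreated groups differed by -0.037 ± 0.19 (SE). Exchanged labels of the treated groups stay open. They were examined with the mean signed log2 CPM of 22 features, changed by 1 mM GlcNAc but not by 250 nM GccF at 30 min. This mean differed by only 0.0290 ± 0.063 between the treated groups, where it had differed by 0.881 ± 0.041 after 10 min of GlcNAc. Its scale is unlike that of the response score. Libraries with GccF after GlcNAc scored -2.23 to -2.02 and those with GccF alone -2.19 to -2.13, near the control libraries of these sets (-2.36 to -2.06). The control of the GlcNAc set differed from that of the 20 nM set by -0.0367 ± 0.098 (SE). Libraries after 10 min of GlcNAc alone scored -1.50 to -1.40, so neither treated group carried that signature over the 22 features. ERT21673-1 and ERT23150-1, the largest falls with GlcNAc alone, stood at 469 ± 64.6 and 18.2 ± 1.28 CPM with 20 nM GccF alone. After GlcNAc they stood at 2092 ± 1469 and 111 ± 78.5 CPM. At 30 min 250 nM GccF lowered them too, to 351 ± 24.4 and 18.5 ± 1.65 CPM, so they cannot decide. ERT23544-1 and ERT23545-1, the largest rises, lay below the control means in both treated groups. An effect of GlcNAc itself, or unequal effective dose between sets, may also account for the larger response, and neither was tested.

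The difference at 0 min appears at a nominal exposure of 0 min. A culture difference unrelated to GccF is argued against as the whole cause, since changes at 0 min followed those by 20 nM GccF in other libraries (r = 0.500 across features). Later harvest of the treated cultures is argued against as the whole cause: r with the drift of controls from 10 to 30 min was 0.0845 (Spearman 0.156), and that drift had r = -0.162 with the changes by 20 nM GccF, that from 0 to 10 min r = -0.00258, where the 0 min changes had 0.500. Without replicate 1 of the GccF group, which had 2.71% low-quality alignments against a control mean of 0.689%, 1501 features were called. A fast response during sampling is a candidate explanation that the labels do not allow to be tested.

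In the 20 nM set the libraries numbered 2 stood apart on component 4 (5.84% of variance) in all 4 groups. Weaker exposure to GccF is argued against as the whole cause, since untreated libraries shared the deviation (r = 0.705 across features between the 2 untreated groups). Numbers 1 and 3 were shared too (r = 0.657 and 0.388). Untreated libraries had no GccF, so weaker exposure of the treated ones in addition stays open. Number 2 had the lowest response score in both treated groups (0.627 without and 1.70 after GlcNAc) and in both untreated groups (-1.11 and -1.08). Another age of the culture may be involved: the deviation had r = -0.168 (Spearman -0.231) with the drift of controls from 0 to 30 min, between the bounds set beforehand, so it stays open. A shared day or batch by number is not given in the labels and no biological explanation was tested.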

How the results depend on the processing

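The setting with O994_ rows removed, that without the libraries numbered 2 and those of the score were chosen after the data were examined. Of 249 recomputed counts 218 stayed within 1.5 times, and of 926 recomputed changes of named features 900 kept direction and side of the threshold, 26 lost the call and 0 reversed. Those lost were in the GlcNAc difference at 20 nM except for 1 of ERT20811-1 with 20 nM GccF (adjusted p up to 0.0548) and 1 of ERT24751-1 in the 30 against 10 min difference (up to 0.0565). The GlcNAc difference (43) was 294 with the replicate block, 164 with DESeq2, 394 with all 33 JH2-2 libraries and 283 without the libraries numbered 2, and the untreated groups (0) gave 1, 5, 4 and 1 under the same settings. With all 33 libraries GlcNAc alone gave 79, the 30 against 10 min difference 318, the controls over time 522 and 20 nM GccF 976. The cause was not tested for any of these. Apart from the GlcNAc difference and the untreated groups (1 against 0), the replicate block changed no count by over 1.5 times. In the GlcNAc difference, where the numbers pair only part of the groups (lowest r = 0.0267), its gain is a hint from the data.

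Leaving out each library gave 1488 to 1522 features for 250 nM at 0 min, 1788 to 1822 at 10 min, 1845 to 1862 at 30 min, 93 to 264 for GlcNAc, 1729 to 1800 for GccF against GlcNAc, 924 to 1126 and 534 to 824 for the differences between times, 566 to 903 for the controls over time, 402 to 549 for 20 nM GccF, 1061 to 1375 after GlcNAc, 1 to 202 for the GlcNAc difference, 0 to 2 for the untreated groups, 761 to 906 for the dose difference and 1319 to 1648 in VI01. Score differences between treated and control groups were lower when the score used all called features. They were 1.14 and 2.22 for 250 nM at 0 and 10 min, where the main score gave 1.56 and 2.96. For 20 nM without and after GlcNAc they were 1.27 and 2.07, where the main score gave 1.75 and 2.76. Between the 2 treated groups at 20 nM the difference was 0.778, where the main score gave 0.977. Not run were the alternatives of the gene lists and of the 3 comparisons across strains, removal of tRNA and rRNA rows in JH2-2, whose files name none, and the fit of all 39 samples. In the simulation of 20 nM GccF, 2-fold changes were recovered in 40% of cases over 2490 features, so small changes at this dose may go uncalled; whether depth or spread sets this was not tested.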

Other observations

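Features that changed together often had consecutive identifiers. After 30 min of 250 nM GccF, 569 of the 1153 features with ERT identifiers that changed at least 2-fold stood in 129 runs of at least 3 consecutive numbers with the same direction, where 1000 shuffles gave 149 on average and 207 at most (permutation p = 0.001, the smallest they can give). The longest run held 12 features. With 20 nM GccF 141 of 399 stood in runs (at most 28 in shuffles), after GlcNAc 345 of 843 (at most 104), and in VI01 252 of 721 features with AAO identifiers (at most 66). GlcNAc alone had 10 of 59 in 3 runs, against at most 3. Fold changes of neighbouring identifiers correlated with r = 0.463 at 30 min of 250 nM GccF and 0.358 with GlcNAc. What the numbering follows is not given in the sources used here.

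In VI01, 9 of the 15 tested rows whose identifiers begin with EBG rose and 1 fell with GccF, with a median log2 fold change of 1.03 when all tested features had a median of -0.0328. With upper-quartile scaling 9 rose and 2 fell (median 0.797, all features -0.272), and with scaling by totals 9 rose and 1 fell. The kind of these rows is not stated, and the group was singled out after its values were seen.

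ERT25445-1 and ERT25446-1, which fell most in untreated cells between 0 and 30 min, had lower means at 10 and 30 min than at 0 min with 250 nM GccF too. These were 836, 127 and 164 CPM at 0, 10 and 30 min for ERT25445-1 and 300.2, 87.6 and 130 CPM for ERT25446-1, against 248, 117 and 2.94 CPM and 167, 120 and 4.82 CPM in controls. The changes between times within GccF libraries were not tested.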
